A study of Xenopus tropicalis with 4 samples.

How the data were processed

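RNA was sequenced from ectodermal explants (animal caps) of Xenopus tropicalis collected at Nieuwkoop-Faber stage 10.5. Embryos had received 22.5 ng of a control morpholino oligonucleotide (MO) or of a Foxh1 MO, and were kept at 25 °C, per the labels. Each group held 2 libraries, numbered 1 and 2. Per the labels' protocols, total RNA was extracted with Trizol and poly(A) RNA was made into libraries with a NEBNext Ultra II kit. Both MOs are named in the labels without their sequence or type, and the labels do not say whether libraries of a group came from separate clutches.

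The deposited tables per library held, per the file headers, an expected count, a TPM, an FPKM, a length and an effective length for each of 28850 genes. The expected counts were the authors' RSEM estimates, and the deposited TPM and FPKM values were on a linear scale. FPKM was not tested further. Per the submitters' processing notes the tools were STAR 2.7.3a, RSEM 1.3.3, edgeR 3.36.0 and R 4.1.2. The genome build and the strand setting used for counting were not given in the sources used here. The authors' comparison table gave, per the file headers, a log2 fold change, a log2 CPM, an F statistic (the score of the edgeR quasi-likelihood test), a p-value and a false discovery rate for 13758 genes. Its direction was checked against the libraries: positive values were higher in the libraries labelled Foxh1 MO. No column of other samples was present (0 columns).

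Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered by group with filterByExpr (minimum count 10, minimum total count 15), which left 13756 of 28850. Libraries were scaled by TMM (factors 1.06, 0.954, 0.959 and 1.03 for control MO 1 and 2 and Foxh1 MO 1 and 2). The quasi-likelihood F test compared the groups with no covariate, 2 residual degrees of freedom and 10.5 prior degrees of freedom. The common biological coefficient of variation was 0.124. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Log2 fold changes were those of the libraries labelled Foxh1 MO minus control MO. A prior count of 2 was used for log2 CPM in library correlations and principal components. The SE of a log2 fold change was its absolute value divided by the square root of F. CPM values were scaled by TMM and are given as mean ± SD of n = 2 libraries. The median log2 fold change over all tested genes was -0.00019.

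Gene symbols were those in the files. The RefSeq table of assembly UCB_Xtro_10.0 served for names, gene types and the order of neighbouring genes only. It held 25857 of the 28850 genes by accession and 26531 by symbol. The share of expected counts in 463 ribosomal RNA gene models was computed per library.

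Before the files were opened, 18 gene lists were fixed. The 5 main lists held Nodal and organizer, endoderm, mesoderm, epidermis and neural ectoderm genes. Another 6 held BMP and ventral, FGF feedback, Wnt target, pluripotency, maternal transcription factor and chromatin partner genes. The remaining 7 were checks: vegetal and germ plasm transcripts, cleared maternal transcripts, DNA damage response, innate immune, endoplasmic reticulum and heat stress, multiciliated cell and ionocyte, and ribosomal protein genes. The ribosomal protein list took all symbols that begin with rpl or rps, so it may also hold genes of other proteins. Some genes stand in more than 1 list. Epidermis and BMP share 6, Nodal and endoderm 4, pluripotency and maternal transcription factors 4, mesoderm and Wnt 4, and Nodal and neural 1. Neural shares 3 genes with maternal transcription factors and 2 with pluripotency. Lists were tested with camera of limma 3.58.1 (two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg over the 18 lists). An estimated correlation and fry were alternatives. Members were also tested with p adjusted over the list alone.

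Named genes followed a rule fixed before the files were opened. It took foxh1 and the 10 genes of largest log2 fold change in each direction among called genes. These needed a gene symbol other than a LOC number, groups that did not overlap in CPM and a higher group mean of at least 5 CPM. It also took the 5 of smallest adjusted p per direction under the same conditions. From each list it took up to 4 called members per direction and the 2 members not called with the highest CPM. Other genes are said to have been chosen after their values were seen. The rule gave 126 genes, of which 3 are not reported here.

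Alternatives fixed beforehand were DESeq2 1.42.0 size factors and its Wald test, upper-quartile factors, no filter, a filter of 1 CPM in 2 libraries, limma-voom, the edgeR exact and likelihood ratio tests, unrounded counts, and an effective length offset. Limma-trend on log2 of TPM with 1 or 0.1 added, the replicate number as a block, each library left out in turn, and other thresholds were also fixed beforehand. With a library left out, the lone library of its group was assumed to vary like the others. For some genes the adjusted p of such fits was smaller than with all 4 libraries, so a kept call is not a stricter test. Removal of ribosomal RNA genes and thinning of all libraries to the smallest total were chosen after the data were seen. So were counts of called list members without each library or with the block, and a comparison of the deposited table with the blocked fit.

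The scripts were tested on simulated counts for this comparison, drawn for 13756 genes from the real means and library sizes with 200 genes changed. They recovered 24 of 67 genes changed 1.5-fold (35.8%), 50 of 67 changed 2-fold (74.6%) and 61 of 66 changed 4-fold (92.4%), and called 19 unchanged genes. The 19 unchanged genes were a larger share of all simulated calls than the calling threshold allows on average. Of 18 simulated lists, the shifted list passed, and 1 list with no shifted members passed as well. In this simulation neither gene calls nor list tests were thus strict, and the real calls may hold more false ones than their adjusted p implies. Raw reads, splicing and single isoforms were not analysed here.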

Results

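Messenger RNA of animal cap ectoderm from early gastrulae was compared between a control MO and a Foxh1 MO group of 2 libraries each. Expected counts summed to 29750009 and 29800530 in control MO 1 and 2, and to 28567827 and 25632619 in Foxh1 MO 1 and 2. Between 17863 and 18244 genes had a count in each library. Ribosomal RNA gene models took 28.3% and 34.0% of the control counts and 32.2% and 29.8% of the Foxh1 MO counts (means 31.1 ± 4.06 and 31.0 ± 1.67, SD, n = 2). Log2 CPM correlated at r = 0.990 across genes within the control pair, 0.988 within the Foxh1 MO pair and 0.972 to 0.980 between groups (genes are not independent replicates). The chi-square of counts per degree of freedom was 35.9 within the control pair, 64.2 within the Foxh1 MO pair and 44.7 to 72.1 between groups. By that measure the Foxh1 MO pair lay within the range of pairs from different groups. The first principal component (64.1% of variance) separated the groups. The labels do not say whether libraries of a group came from separate clutches, so each p measures the spread between these samples, which may be technical.

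Foxh1 is a forkhead transcription factor that acts with Smad2 in Nodal signalling, and the comparison asks which ectodermal transcripts depend on it. The foxh1 transcript stood at 79.3 and 71.2 CPM in control MO 1 and 2 and at 264 and 174 CPM in Foxh1 MO 1 and 2. It was thus 2.91-fold higher in the libraries labelled Foxh1 MO (log2 fold change 1.54, SE 0.19, edgeR quasi-likelihood adjusted p = 0.000431). Without each library in turn the log2 fold change was 1.21 to 1.81. A transcript level does not measure the protein, and the type of MO is not in the labels, so the level does not show that Foxh1 was depleted. Directions are therefore stated for the libraries labelled Foxh1 MO: "rose" and "higher" mean higher there than in control MO, "fell" and "lower" the reverse.

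Among called genes with a symbol and a mean of at least 5 CPM in the higher group, the largest changes were in genes of varied function. Among genes that rose were l3mbtl1, which encodes a chromatin protein that binds methylated histones (15.2-fold, 0.350 ± 0.0466 to 5.38 ± 0.0851 CPM), and the kinase gene sgk2 (9.4-fold, 1.06 ± 0.145 to 9.96 ± 1.76 CPM). Others were ap5s1 (6.38-fold), dpysl4 (6.06-fold), rpn2, a subunit of the oligosaccharyltransferase (5.37-fold), ttc31 (5.08-fold), the chondroitin synthase gene chsy1 (4.53-fold), anks3 (4.35-fold), vtcn1 (4.18-fold) and znf644 (3.54-fold). Among genes that fell was kirrel2, which encodes an adhesion protein of the immunoglobulin superfamily (8.73-fold lower, 48.2 ± 1.38 to 5.52 ± 0.711 CPM). The mitochondrial transporter gene abcb10 was 6.58-fold lower, slc5a8.1 6.44-fold, the homeobox gene hmx3 6.1-fold, mybl1 5.94-fold and mto1 5.42-fold. Values for phlda1, the protocadherin gene pcdh8 and the membrane metalloproteinase gene mmp14 were 5.34, 5.30 and 4.61 times lower. The smallest adjusted p by edgeR were 6.19e-06 for ttc31 (log2 fold change 2.35, SE 0.14) among genes that rose and 1.71e-06 for kirrel2 (-3.13, SE 0.16) among those that fell. The naming rule required that the groups did not overlap. Without each library in turn, none of these genes changed sign. The log2 fold change was then 2.28 to 2.41 for ttc31 and -3.26 to -3.01 for kirrel2.

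In all, 574 genes rose and 560 fell of 13756 tested (8.24%, edgeR quasi-likelihood test, Benjamini-Hochberg), 174 and 336 of them by at least 2-fold. Of the 1134 called genes 1086 were protein coding. The groups did not overlap in CPM for all 1134, which follows largely from the calling with 2 libraries per group. They did not overlap for 6983 of all tested genes (50.8%). By chance a single gene would do so in 33.3% of cases, but all genes share the same 4 libraries. The counts depended on single libraries: without Foxh1 MO 1 they were 853 higher and 1493 lower, and without Foxh1 MO 2 they were 413 and 337.

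**Figure D1:**
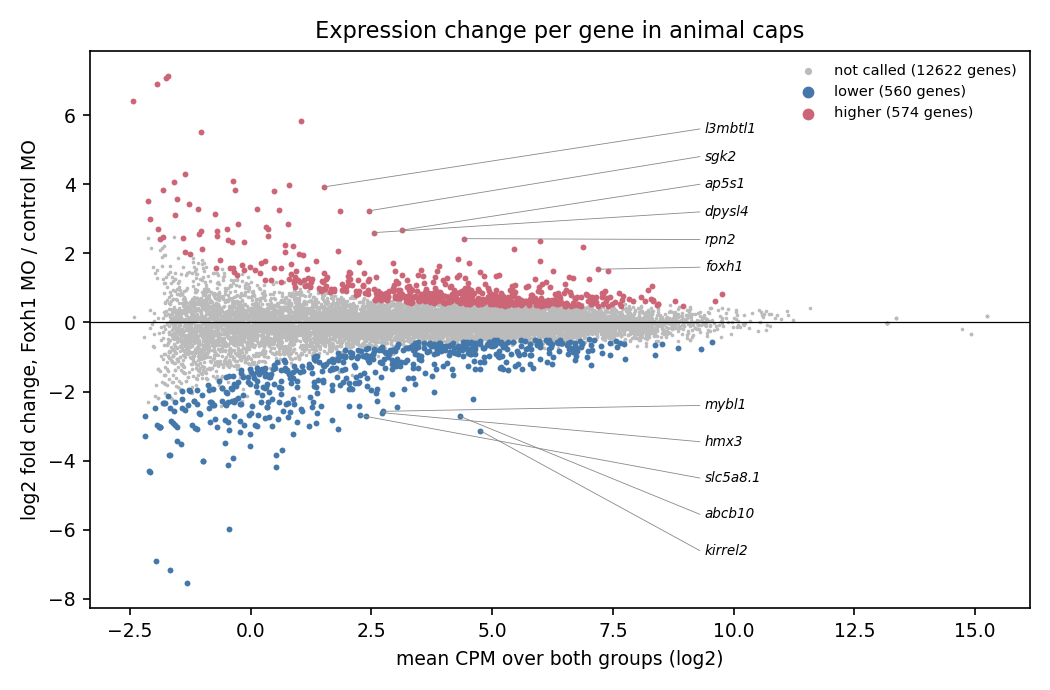
Log2 fold change of the libraries labelled Foxh1 MO over control MO (vertical axis) against mean CPM (log2 scale, horizontal axis), 1 point for each of 13756 genes. Colours mark the 574 genes called higher and the 560 called lower, and labels mark foxh1 and, of the named genes, the 5 of largest change per direction.

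A subset of neural genes fell, and a subset of epidermis genes rose, in the libraries labelled Foxh1 MO. Of 28 tested neural ectoderm genes, 12 fell, 0 rose and 16 did not pass, with 14 lower and 1 higher when adjusted over the list alone; 24 of 28 had a negative sign. The neural plate gene sox2 was 2.34-fold lower (185 ± 5.14 to 79.1 ± 9.89 CPM; log2 fold change -1.23, SE 0.14, edgeR adjusted p = 0.000349), and its relatives sox3 and sox1 fell 1.55-fold and 4.96-fold. The homeobox genes otx1 (58.3 to 22.6 CPM), irx3 (4.04 to 1.52 CPM) and pou3f2 (2.47 to 0.927 CPM) and the forkhead gene foxd4l1.2 (1.27 to 0.482 CPM) fell. The other 5 that fell were named after their values were seen: irx1 (51.4 to 20.5 CPM), zic2 (98.5 to 65.6 CPM), otx2 (13.8 to 7.32 CPM), neurog3 (4.73 to 2.31 CPM) and pax3 (1.75 to 0.705 CPM). Log2 fold changes of sox11 and gmnn, both not called, were 0.01 and -0.33. The sox11 value turned to -0.18 without Foxh1 MO 1 and to -0.12 without control MO 1. The list lay below other genes by camera (adjusted p = 4.16e-10), but not with an estimated correlation (adjusted p = 0.610 with an estimated correlation). Without Foxh1 MO 2 the count fell to 7, since zic2, pax3, neurog3, pou3f2 (adjusted p = 0.0788) and foxd4l1.2 lost their calls; without control MO 2 it was 8, without sox3 (adjusted p = 0.196), zic2, pax3 and foxd4l1.2. The call of foxd4l1.2 ended whichever library was left out (largest adjusted p = 0.217) and that of pax3 also without Foxh1 MO 1 (adjusted p up to 0.228).

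Of 36 tested epidermis genes, 12 rose, 3 fell and 21 did not pass, with 16 higher and 6 lower when adjusted over the list alone. The genes that rose by the most were elf3 (2.99-fold), dlx3 (2.32-fold, 5.66 ± 1.55 to 13.1 ± 2.53 CPM), msx1 (1.94-fold) and foxi1, a regulator of ionocytes (1.87-fold, 43.1 ± 10.2 to 80.6 ± 24.2 CPM). The list also held ventx1.2, ventx1.1 and gata2, given with the BMP genes. Named after their values were seen, tfap2a, an activator of epidermal genes, rose from 241 to 386 CPM, the grainyhead-like gene grhl1 from 113 to 199 CPM, the keratin gene krt70 from 249 to 392 CPM, klf5 from 77.8 to 111 CPM and upk3b from 65.7 to 98.3 CPM. Those that fell were tfap2e (2.08-fold lower), krt12.4 (1.96-fold lower) and foxi2 (88.0 to 58.8 CPM). The log2 fold change of epcam was 0.03, and -0.01 without Foxh1 MO 2; that of cldn6.1 was -0.43, and neither passed. The list lay above other genes by camera (adjusted p = 0.0398; adjusted p = 0.610 with an estimated correlation). Without control MO 1 that p was 0.127 and only 6 genes were called higher, with tfap2a (adjusted p = 0.106), krt70 (0.152), klf5, foxi1, ventx1.1 and gata2 no longer called. Without Foxh1 MO 2 the calls of elf3 (adjusted p = 0.268), foxi1, krt12.4, klf5 and upk3b (up to 0.290) ended, and without control MO 2 those of krt12.4, foxi2, klf5 and upk3b; foxi2 was lost without control MO 1 as well.

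**Figure D2:**
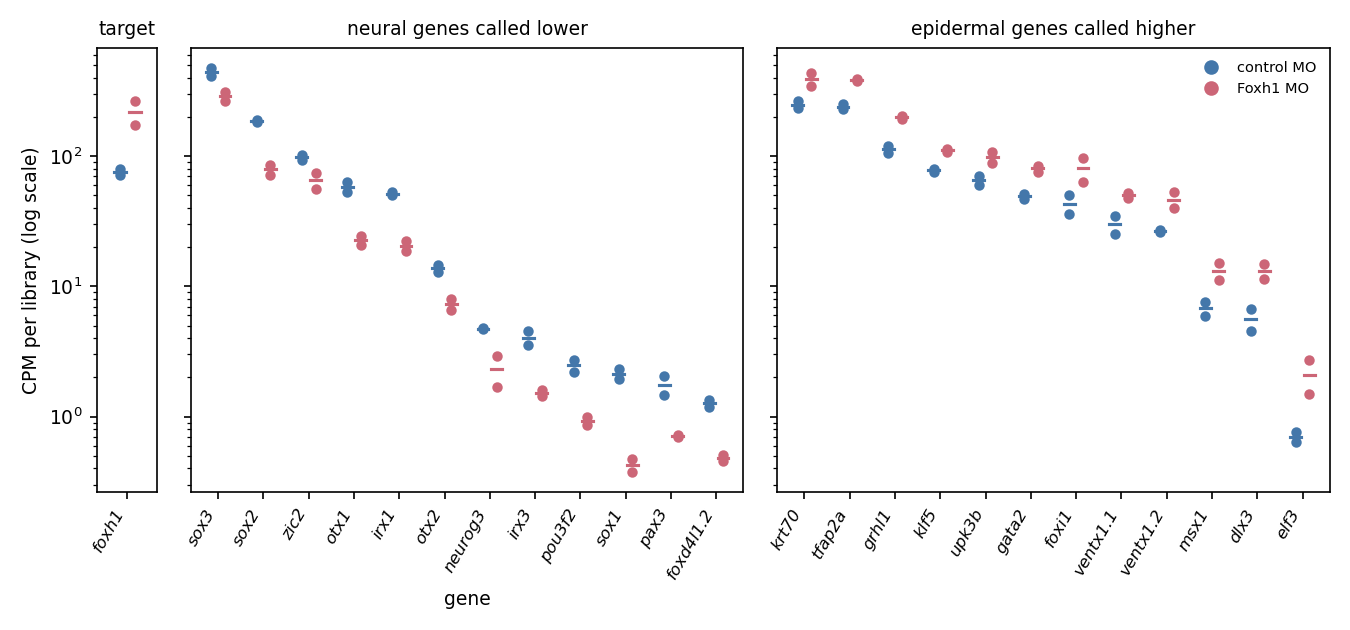
CPM per library (log scale) of foxh1, the 12 neural genes called lower and the 12 epidermis genes called higher. Points are libraries (n = 2 per group) and bars the group means; foxh1 rose from 75.2 to 219 CPM and sox2 fell from 185 to 79.1 CPM.

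Several organizer genes were close to absent in the libraries labelled Foxh1 MO, from low levels in control caps. Of 15 tested Nodal and organizer genes, 7 fell, 1 rose and 7 did not pass, with 9 lower and 2 higher when adjusted over the list alone. The BMP antagonist gene chrd.1 (chordin) was 12.9-fold lower (2.92 ± 0.293 to 0.221 ± 0.0998 CPM), the BMP-like ligand gene admp 15.1-fold (1.46 ± 0.268 to 0.0925 ± 0.0241 CPM), mix1 5.85-fold and the activin antagonist gene fst (follistatin) 3.68-fold. Of the others that fell, lhx1 (4.38 to 1.32 CPM), eomes (5.71 to 2.93 CPM) and otx2 were named after their values were seen. The notochord gene not rose 1.58-fold, from 60.5 to 95.4 CPM. For pkdcc.1 and lefty, not called, the log2 fold changes were -0.46 and 0.61. The organizer gene gsc was untested at this depth, with 16 and 8 counts in the controls and 1 and 0 in the libraries labelled Foxh1 MO; it was named after its values were seen. Another 14 of the 30 members in the files were also too low to test. The list lay below other genes by camera (adjusted p = 1.52e-08; adjusted p = 0.610 with an estimated correlation). The rise of not ended without control MO 1, control MO 2 or Foxh1 MO 1 (adjusted p up to 0.0734), and the fall of eomes without control MO 2 or Foxh1 MO 2 (up to 0.0868).

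Mesoderm and endoderm genes moved both ways. Of 24 tested mesoderm genes, 2 rose, 5 fell and 17 did not pass (3 higher and 9 lower when adjusted over the list alone). The paraxial protocadherin gene pcdh8 fell from 6.92 to 1.3 CPM, and foxd3, foxc2 and evx1 were 2.59-fold, 2.51-fold and 2.38-fold lower; eomes was the other. The Notch ligand gene dlc rose 1.80-fold and cdx4 1.98-fold. The mesoderm gene tbxt (brachyury), named after its values were seen, had a log2 fold change of 0.26 (edgeR adjusted p = 0.656), and fgfr4 and bmp4 had 0.36 and 0.19, all not called. Camera gave an adjusted p of 0.116, downward, and 0.00800 without control MO 1. Without Foxh1 MO 2 only 1 mesoderm gene was called lower, since foxd3, foxc2, evx1 and eomes lost their calls (adjusted p 0.115, 0.0812, 0.0903 and at most 0.0868), and cdx4 was lost without Foxh1 MO 2 or control MO 1 (up to 0.116). Of 13 tested endoderm genes, 1 rose, 2 fell and 10 did not pass (the same counts when adjusted over the list alone): darmin rose 9.80-fold from 0.201 to 2.01 CPM, while mix1 and sox17b.1 (2.08-fold lower) fell. Log2 fold changes of vegt and gata6, not called, were -0.24 and -0.44. Camera gave an adjusted p of 0.116, downward, and 0.00793 without control MO 1. The call of sox17b.1 ended without either library labelled Foxh1 MO (adjusted p up to 0.0735).

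**Figure D3:**
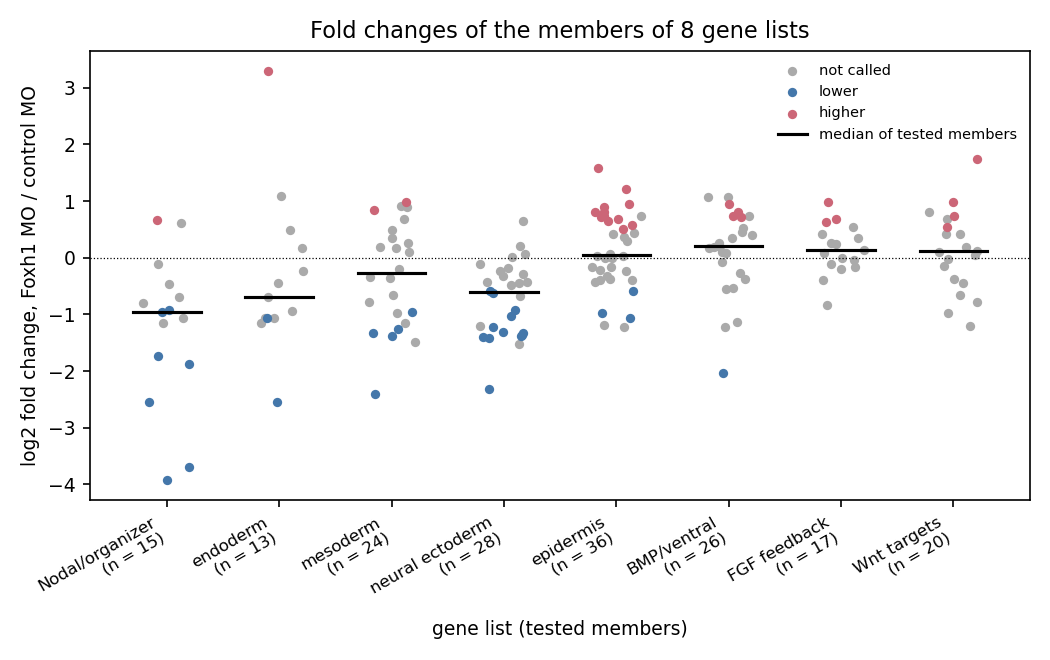
Log2 fold change of each tested member of 8 gene lists (points, coloured by call) with the list median (bar). The medians were -0.96 for Nodal and organizer, -0.61 for neural ectoderm and 0.05 for epidermis genes.

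With all 4 libraries, more genes of BMP signalling, FGF feedback and Wnt signalling rose than fell. Of 26 tested BMP and ventral genes, 4 rose, 1 fell and 21 did not pass (7 higher and 3 lower when adjusted over the list alone). The ventral homeobox genes ventx1.2 (26.6 to 46.5 CPM), ventx1.1 (30.05 to 50.02 CPM) and msx1 and the zinc finger gene gata2 (49.1 to 80.5 CPM) rose; all 4 are also among the epidermis genes. The T-box gene tbx2 fell from 1.15 to 0.276 CPM, and id3 and bmp7.2, not called, had log2 fold changes of 0.17 and -0.26. Camera placed the list above other genes (adjusted p = 0.0399; adjusted p = 0.610 with an estimated correlation), but not without control MO 1 (adjusted p = 0.108), where 2 genes were higher and 2 lower and ventx1.1 and gata2 lost their calls (adjusted p 0.152 and 0.0716); tbx2 was lost without Foxh1 MO 2 (0.208). Of 17 tested FGF genes, 3 rose, 0 fell and 14 did not pass (3 and 0 when adjusted over the list alone): cdx4, the feedback inhibitor gene spry2 (1.6-fold) and fos (1.55-fold). Log2 fold changes of etv1 and fgfr4, not called, were -0.03 and 0.36; etv1 stood at 0.14 without Foxh1 MO 2 and 0.02 without control MO 1. Camera gave 0.155, and 0.0377 without control MO 2 or 0.0162 without Foxh1 MO 2; 0 FGF genes were called by edgeR without control MO 1, and 3 were higher and 3 lower without Foxh1 MO 1; fos was also lost without control MO 2 or Foxh1 MO 1 (adjusted p up to 0.136). Of 20 tested Wnt genes, 4 rose, 0 fell and 16 did not pass (5 higher and 3 lower when adjusted over the list alone): hoxd1 (3.33-fold), cdx4, and the pathway inhibitor genes znrf3 (1.67-fold) and axin2 (1.46-fold). Those of fzd7 and sp5l, not called, were 0.05 and 0.11; without Foxh1 MO 1 they were -0.10 and -0.14. Camera gave 0.184, and 0.0358 without Foxh1 MO 2. Without control MO 1 only hoxd1 was called higher (adjusted p of znrf3 0.0641) and 2 Wnt genes were lower, and without Foxh1 MO 1, 3 were higher and 2 lower; axin2 was lost without control MO 1, control MO 2 or Foxh1 MO 1 (up to 0.252).

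More pluripotency and maternal transcription factor genes fell than rose. Chromatin genes were called at about the share of all tested genes (8.24%). The falls partly repeat those of neural genes: sox2 and sox3 stand in both lists, and otx1 in the maternal and vegetal lists. Of 20 tested pluripotency genes, 4 fell, 0 rose and 16 did not pass (5 lower and 0 higher when adjusted over the list alone): sall4 (807 ± 35.2 to 478 ± 88.0 CPM), foxd3, sox2 and sox3. Log2 fold changes of pou5f3.2 and pou5f3.1, relatives of mammalian Oct4, were -0.07 and -0.08, both not called, and 0.12 and 0.17 without Foxh1 MO 2. Camera gave 0.116, and 0.0233 without Foxh1 MO 1; foxd3 was lost without Foxh1 MO 2 (0.115) and sox3 without control MO 2 (0.196). Of 31 tested maternal transcription factor and transducer genes, 3 rose, 7 fell and 21 did not pass (4 higher and 8 lower when adjusted over the list alone). Besides foxh1, creb1 (55.5 ± 3.32 to 138 ± 7.73 CPM) and the Nodal transducer gene smad2 (59.0 to 93.2 CPM) rose. The TGF-beta ligand gene gdf3 fell 4.64-fold and hes7.1 2.48-fold, beside otx1, sox2, sox3 and foxi2, and foxr1, named after its values were seen (7.03 to 3.50 CPM). For ctnnb1, not called, the log2 fold change was 0.11. Camera placed this list below other genes (adjusted p = 0.0399; adjusted p = 0.610 with an estimated correlation), but not without control MO 1 (0.0655), control MO 2 (0.0654) or Foxh1 MO 2 (0.197). Without control MO 1, smad2 (0.0933) and foxr1 (0.0504) lost their calls. Of 47 tested chromatin partner genes, 3 rose, 1 fell and 43 did not pass (5 higher and 2 lower when adjusted over the list alone). Among them gatad2a (1.53-fold) and the PRC2 subunit gene eed (1.45-fold) rose and chd3 fell 1.88-fold. Smarcc1 and chd4, not called, had log2 fold changes of -0.22 and -0.18 (chd4 0.08 without Foxh1 MO 2). The list's median was -0.00236, its mean was 0.02 and camera pointed upward (adjusted p = 0.575), so the signs differed. Without Foxh1 MO 1 camera pointed downward (0.408) and 6 rose and 12 fell; gatad2a was lost without either control library (up to 0.151) and eed without control MO 1, control MO 2 or Foxh1 MO 2 (up to 0.176).

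In 6 of the 7 lists that mark stage, tissue and stress, more genes fell than rose. The ribosomal protein list was the exception. Of 17 tested vegetal and germ plasm transcripts, 2 fell (otx1 and rras2, 1.53-fold lower), 0 rose and 15 did not pass (2 and 0 when adjusted over the list alone; camera 0.155), with log2 fold changes of -0.17 and -0.23 for tdrd6 and trim36, not called. Of 25 tested cleared maternal transcripts, 4 fell, 0 rose and 21 did not pass (4 lower and 1 higher when adjusted over the list alone): cpeb1 (10.9 ± 7.59 to 4.28 ± 0.452 CPM), cdc25b (1.77-fold lower), patl2 (1.52-fold lower) and ccna1 (1.51-fold lower). Their median log2 fold change was 0.02, the mean was -0.10 and camera pointed downward (0.430), and ccnb1.2 and ccne1, not called, stood at 0.11 and -0.07. Without Foxh1 MO 2 only ccna1 was left among these 4 (adjusted p of cdc25b 0.0511), and rras2 was not called; without control MO 1 cpeb1 (0.558) and ccna1 (0.333), and without control MO 2 patl2 (at most 0.104) and rras2 (at most 0.250), lost their calls. The ccnb1.2 value was -0.00625 without Foxh1 MO 2.

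Of 31 tested DNA damage response genes, 2 rose, 5 fell and 24 did not pass (3 higher and 7 lower when adjusted over the list alone). The cell cycle inhibitor gene cdkn1a (5.04 ± 2.53 to 1.43 ± 0.164 CPM), sesn1 (4.14-fold lower), gadd45b (3.67-fold lower) and plk3 (2.32-fold lower) fell, as did plk2, named after its values were seen (31.1 to 19.2 CPM), while zmat3 and aen rose 1.5-fold and 1.45-fold. The log2 fold change of bax, not called, was 0.08. Camera gave 0.0471, downward (adjusted p = 0.610 with an estimated correlation), and 0.273 without control MO 2 and 0.157 without Foxh1 MO 1. Calls ended for zmat3 whichever library was left out (up to 0.134), aen without control MO 1, control MO 2 or Foxh1 MO 2 (up to 0.175), and plk2 without control MO 2 or Foxh1 MO 2 (up to 0.283). Of 24 tested innate immune genes, 1 rose, 5 fell and 18 did not pass (the same counts when adjusted over the list alone; camera 0.116): nfkbia rose 1.84-fold, cebpd (2.73-fold), irf7 (2.61-fold), the complement gene c3 (2.11-fold) and irf1 (1.68-fold) were lower, and socs3, named after its values were seen, fell from 26.8 to 17.8 CPM. Without Foxh1 MO 2 irf7 (0.0907), irf1 (up to 0.0654) and socs3 (up to 0.208) were lost, and only 2 were lower; irf1 and socs3 were also lost without control MO 1 and socs3 without control MO 2. Values of ifi30 and rela, not called, were 0.11 and 0.21, and ifi30 stood at -0.00363 without control MO 2. Of 30 tested endoplasmic reticulum and heat stress genes, 1 rose, 3 fell and 26 did not pass (3 higher and 4 lower when adjusted over the list alone): manf rose 1.64-fold, and ddit4 (1.95-fold), pdia4 (1.73-fold) and dnajb1 (1.67-fold) were lower, the last not without control MO 2 or Foxh1 MO 2 (up to 0.123). The median was 0.05, the mean was -0.02 and camera pointed downward (0.760), or upward without Foxh1 MO 1 (0.606); hspa8 and calr, not called, had 0.36 and -0.37.

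Of 16 tested multiciliated cell and ionocyte genes, 1 rose (foxi1), 3 fell and 12 did not pass (2 higher and 4 lower when adjusted over the list alone). The ciliary regulator foxj1 was lower, from 46.9 ± 7.27 to 23.4 ± 7.93 CPM, as were tp73 (4.06 ± 3.85 to 0.745 ± 0.227 CPM) and dmrt2 (2.57-fold lower). Log2 fold changes of rfx2 and atp6v1a, not called, were -0.31 and -0.20 (atp6v1a 0.11 without Foxh1 MO 2). Camera gave 0.243, and 0.0285 without control MO 1; tp73 was lost without control MO 2 (0.424), dmrt2 without control MO 1 (0.0996), and foxi1 without control MO 1 or Foxh1 MO 2 (up to 0.0914). Of 87 tested genes of the ribosomal protein list, taken by symbol prefix, 12 rose, 0 fell and 75 did not pass (13 higher when adjusted over the list alone). A positive sign was held by 74. Rpl37 (1.72-fold), rpl32 (1.68-fold), rps3a (1.6-fold) and rpl18 (1.6-fold) rose by the most, and rpl6 and rpl3, not called, had log2 fold changes of 0.31 and 0.27. Camera placed them above other genes (adjusted p = 2.97e-06; adjusted p = 0.659 with an estimated correlation). The count was 0 by edgeR without control MO 1, 15 without control MO 2, 25 without Foxh1 MO 1 and 1 (rpl32) without Foxh1 MO 2.

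The authors' table listed 13758 genes, 553 higher and 691 lower at a false discovery rate under 0.05. Its log2 fold changes correlated with those given here at Pearson r = 0.999 and Spearman rho = 0.999 across 13753 shared genes, which come from the same libraries and are not independent evidence. Of the called genes 1048 were shared, all 1048 with the same sign, 195 were called in the authors' table only and 86 here only. In a comparison chosen after the data were seen, a fit of the unrounded counts with the replicate number as a term gave all 13758 of the authors' log2 fold changes within a tolerance of 1e-06. Without that term 4 of 13758 matched. That fit called 545 genes higher and 700 lower, 1214 of them among the authors' 1244. The smallest p was 5.92e-46 in the authors' table and 1.24e-10 here. For 12083 genes (87.8%) the authors' p equalled, within 0.1%, that of their F statistic with infinite denominator degrees of freedom. The blocked fit of unrounded counts had 1 residual and infinite prior degrees of freedom, against 2 and 10.6 without the block. With the residual and prior degrees of freedom of the main fit, the authors' F statistics gave 708 fewer calls. Those degrees of freedom belong to a fit without the block, with other variance estimates. The 708 is thus not a count of false calls, and the main fit itself shared 1048 calls with the authors.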

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

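Scaling, test, rounding, length offset, removal of ribosomal RNA genes and thinning (the last 2 chosen after the data were seen) left the counts of 574 higher and 560 lower within 1.5 times. With the lone library of a group assumed to vary like the others, leaving out 1 library gave 388 to 853 higher and 337 to 1493 lower, foxh1 from 1.21 to 1.81, 7 to 12 neural genes called lower and 6 to 14 epidermis genes called higher. No filter gave 862 lower; log2(TPM + 0.1) gave 375 higher. A 2-fold threshold gave 174 and 336, an adjusted p under 0.01 gave 210 and 220, and one under 0.10 gave 874 higher, all by construction. Limma-trend on log2(TPM + 1) without a filter called 0 in either direction (2893 of 20557 had an unadjusted p under 0.05) and gave foxh1 1.48 (adjusted p = 0.167); with a filter it called 386 and 465, and DESeq2 called 484 and 422. List tests with an estimated correlation gave 0.610 for Nodal, neural and epidermis genes; fry gave 0.167, 0.167 and 0.245. The epidermis list gave 0.0618 without a filter. Leaving out 1 library gave 0.00972 to 0.127 for epidermis, 0.00793 to 0.351 for endoderm and 0.00800 to 0.273 for mesoderm. The causes were not tested. Of 92 called named genes, 53 kept their call without each library in turn and 39 lost it without at least 1; none changed sign. Some adjusted p were smaller without 1 library than with all 4, so a kept call is not a stricter test. Of the 92, the DESeq2 Wald test lost 13: sox17b.1, elf3, tfap2e, krt12.4, pou3f2, foxd4l1.2, tbx2, fos, rras2, cpeb1, zmat3, irf7 and dmrt2. Limma-voom lost 6: foxd4l1.2, fos, rras2, cpeb1, zmat3 and tp73.

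Signs turned for genes near 0 that were not called. The epcam log2 fold change was -0.0117 with each of the 3 TPM settings (-0.0116 to 0.0690 without 1 library), and the sox11 log2 fold change was -0.00281 with the 1 CPM filter, -0.0340, -0.0341 and -0.0340 with the TPM settings and -0.00958 thinned (-0.18 to 0.18). Without 1 library, etv1 ranged over -0.23 to 0.14, fzd7 -0.10 to 0.18, sp5l -0.14 to 0.32, pou5f3.2 -0.30 to 0.12, pou5f3.1 -0.37 to 0.17, chd4 -0.51 to 0.0828, ccnb1.2 -0.00625 to 0.21, ifi30 -0.00363 to 0.23 and atp6v1a -0.60 to 0.11. The list tests of chromatin partners (0.0723 to 0.925) and endoplasmic reticulum stress (0.433 to 0.925) turned without Foxh1 MO 1.

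Libraries with the same number were not shown to pair: their deviations from the group means correlated at -0.0821 across 13756 genes. With the number as a block, 546 genes were higher and 699 lower, 1046 of the 1134 among them. With unrounded counts this fit had 1 residual and infinite prior degrees of freedom, against 2 and 10.6 without the block. The edgeR quasi-likelihood adjusted p of foxh1 was 2.77e-12 with the block, against 0.000431 without it. A gene call kept with the block is thus not a stricter test. The block ended the maternal transcription factor call (0.0684) and those of axin2, eed, zmat3, aen, klf5, rps7 and rpl10a, and no other call of a list, a list member or a named gene. Lists whose counts moved were then mesoderm (2 higher, 7 lower), epidermis (11, 3), Wnt (3, 2), pluripotency (0, 5), chromatin (2, 3), DNA damage (0, 5), endoplasmic reticulum stress (2, 3), multiciliated (2, 4) and ribosomal protein (10, 0). In simulation, with a smaller share of genes changed than was called here, 35.8% of 1.5-fold changes were recovered. Smaller changes may thus often have gone undetected at this depth and number of libraries, though that rate need not hold for the data. The simulation also called 19 unchanged genes, a larger share of its calls than the calling threshold allows on average. It passed 1 list with no shifted members. Adjusted p close to the threshold are therefore weak evidence, as for the epidermis, BMP, maternal transcription factor and DNA damage lists.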

Other observations

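Beyond the fixed lists, gene families were compared by shared symbol stem, a test chosen after the results were seen. Of 214 families with at least 8 tested members, in 428 one-sided Fisher's exact tests, 0 passed Benjamini-Hochberg adjustment. Closest were the protocadherins, of which 4 of 9 fell (pcdh7, pcdh8, pcdh10 and pcdh18; adjusted p = 0.0867), and the sox genes, of which 5 of 17 fell (sox1, sox2, sox3, sox8 and sox17b.1; adjusted p = 0.0867). Genes of the ribosomal protein list, taken by symbol prefix, had a median log2 fold change of 0.25 (n = 87). It was 0.04 for 4742 other genes in their range of length and level. The median effective lengths of 361 and 1818 bases were not well matched. With tested genes split by effective length into 4 equal parts, the medians from short to long were 0.06, 0.02, -0.02 and -0.07.

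Genes that lie next to each other were often called in the same direction. L3mbtl1 (log2 fold change 3.92) lies next to sgk2 (3.23), and sgk2 lies next to LOC116407945 (5.83), whose model overlaps it. Hmx2 (-3.01) fell beside hmx3 (-2.61), dlx1 (-1.71) beside dlx2 (-1.12), and zic5 (-1.83) beside zic2 (-0.59). These genes were chosen after their values were seen.

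All tests below were chosen after the result was seen, except those of near-identical neighbours and of overlapping gene models. The neural genes called lower and epidermis genes called higher might come from unequal ribosomal RNA or depth: the group means of the ribosomal RNA share differed by -0.154 percentage points (larger SD 4.06), and 11 neural genes were still called lower after thinning, which excludes both as the sole cause. Younger explants in the group labelled Foxh1 MO could have the same effect. There 4 more cleared maternal transcripts were called lower than higher, but only 1 was lower without Foxh1 MO 2, and how far they would rise in younger explants is not known, so this stays open. Less marginal zone tissue could lower neural inducers. The mesoderm median was -0.26 (95% bootstrap interval over genes -0.96 to 0.26), which holds both 0 and the neural median of -0.61. These genes come from the same 4 libraries, so the interval does not measure the spread between explants. The Nodal and organizer list, with a median of -0.96, was not used in the test. Less marginal zone tissue thus stays open.

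The higher foxh1 transcript could come from reads of an overlapping or adjacent gene or from a general delay in clearance of maternal RNA. Of annotated genes, 0 overlapped foxh1 by the RefSeq annotation, and its neighbours ppp1r16a and tonsl had log2 fold changes of -0.22 and 0.10, not called, which argues against the first; reads of similar genes elsewhere stay open. The 25 cleared maternal transcripts had a median log2 fold change of 0.0214 (SD 0.38) and none above 0.44, against 1.54 for foxh1, and their median stayed below the foxh1 value by more than the SD without each library and with the block. As a set they did not rise as foxh1 did, which argues against a delay that raises all of them by this size. All 25 passed the low-count filter, and ccnb1.2 stood at a mean of 1020 CPM in control MO, so clearance of the members by this stage was not shown here. How far a delay would raise each of them is not known. A general delay thus stays open, as does slower decay of the foxh1 transcript itself.

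Of neighbouring tested genes, 89 pairs were called in the same direction, against a mean of 46.6 in 100000 shuffles of the calls (1.91 times, one-sided permutation p = 1e-05, the smallest these shuffles give), and 33 in opposite directions against 46.7. Reads shared by near-identical genes could cause this. Without genes that had fractional counts the ratio was 1.57 (63 against 40.01, p = 0.00027, permutation), which excludes it as the sole cause. Overlapping models, which might be counted without strand, were only 4 of the 89 pairs. Without these the ratio was 1.92 (85 against 44.4, permutation p = 1e-05), which excludes overlap as the sole cause. Neighbours whose models do not overlap were not covered by that test. Neighbours that share a symbol stem were 7 of the 89 pairs, and without them the ratio was 1.79 (82 against 45.9, permutation p = 1e-05), which excludes these alone. Without LOC symbols and shared stems together it was 1.18 (permutation p = 0.161, 11123 genes), and without the pairs that hold a LOC symbol 42 stood against 35.1 (permutation p = 0.136). The 47 pairs that hold a LOC symbol stood against 11.6, and the families of these genes were not assigned, so a role of gene families stays open.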
